A study of Arabidopsis thaliana with 6 samples.

How the data were processed

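Total RNA was extracted from young rosette leaves of Arabidopsis thaliana, depleted of ribosomal RNA and sequenced as stranded single-end libraries on an Ion Proton instrument, per the labels. The 6 libraries form 3 groups of 2: the white leaf border of the flv/dot4 T-DNA line (FLV border), the green leaf border of Col-0 wild type (WT border) and the leaf centre of Col-0 (WT centre). Plants were at Boyes stage 1.13, grown at 18 to 21 °C under at most 90 µE of light. The labels give no harvest time, library batch or sequencing date, and nothing says that the replicates are separate plants. The p-values below therefore measure only the spread between these libraries.

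The deposited values are raw counts, 1 table per library, from 20448315 to 33214552 counts. Per the file headers they were written by a program named sam2pkm, which counted mapped reads per gene model and gives the length of each model. The labels name TAIR10 as the genome build. The aligner, the handling of reads that map more than once and the use of strand are not stated. The sum of the counts equalled the mapped reads of the header in every file. The header number may itself be that sum, so this does not show that each read was counted once. Each table holds the same 33602 gene models, of which 32835 have a name or type in the TAIR10.1 reference annotation. Only 37.5% of the models with a reference transcript had its exact length. Positions are therefore given from the reference for DOT4 and rpoC1 alone. Reads from near-identical genes cannot be separated in such counts. This concerns plastid genes in the inverted repeat, mitochondrial genes with a copy on chromosome 2, LHCB1 paralogs and a tandem pair of DUF295 genes.

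Before the data were examined, 29 gene lists with 467 members, the tests, the rule for named genes and the alternatives in normalisation, filter, tool and libraries were fixed. The lists cover the organelle genomes, nuclear photosynthesis genes, plastid and mitochondrial stress, hormones and defence, cell division, and markers of xylem, phloem, guard cells, trichomes and epidermis. The names of the list members were checked against the reference. The 115 organelle members were checked by length: 96 had the length of the expected gene in the reference, 9 differed and 10 had no length in the reference to compare with.

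The 15 loci for rRNA were left out before library sizes were computed, because the libraries were depleted of rRNA. Genes were kept by filterByExpr of edgeR 4.0.16 with the group as design, which left 21852 genes: 21587 nuclear, 125 plastid and 140 mitochondrial. Library sizes were scaled by TMM. A quasi-likelihood model (glmQLFit with robust=TRUE, glmQLFTest) with 1 mean per group was fitted to all 6 libraries, so that the 3 pairs share 1 estimate of the spread. It had 3 residual degrees of freedom and a common biological coefficient of variation of 0.456. Two-sided p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and genes under 0.05 are called. Normalised counts are CPM (counts per 1e6) of the TMM-scaled library size. Errors after a log2 fold change are standard errors of the model. The spread of a group share is the standard deviation of 2 libraries.

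Each list with at least 5 tested members was tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Members were also counted with p-values adjusted over the list alone. With 2 libraries against 2 there are 6 splits, and the smallest exact two-sided permutation p is 0.333. Shares of counts were compared by their values and spread, and no other test was run on them. For a share in a single library the 95% exact Clopper-Pearson interval is given. Such intervals cover counting error only.

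Per comparison, the named genes are DOT4, rpoC1, up to 6 called protein-coding genes in each direction with the largest fold change, a mean of at least 5 CPM over the 4 libraries and no overlap between the groups, and of each list up to 4 members by smallest p where the list or a member passed, otherwise up to 2. Other genes that the text names are outside this rule, and for some the text says that they were chosen after their values were seen. The neighbours of DOT4, ACC1, the single clock genes and the DUF295 members not called are to be read in the same way.

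The alternatives fixed beforehand were RLE scaling, scaling from nuclear genes, library totals with no TMM, no filter, rRNA loci kept, only the 4 libraries compared, the library number as a block, each library left out in turn, robust=FALSE, DESeq2 1.42.0 and limma-voom. Where 1 library was left out, the lone library of its group is assumed to vary like the other groups. After the data were seen, 3 alternatives were added: an offset that removes each library's trend of log2 CPM on gene length, the same with GC content, and a fit of nuclear protein-coding genes only. The 2 comparisons share the WT border libraries. Their correlation across genes was therefore set against 20 simulations with no group effect that share the same control libraries.

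The edgeR fit was tested on simulated data with 200 changed genes in each of 5 runs per comparison. In FLV border against WT border it recovered 0.8% of genes changed by 1 on the log2 scale, 8.4% at 2, 48.4% at 3 and 83.6% at 4, with a mean of 8.4 false calls per run. In WT border against WT centre the shares were 0, 9.6, 42.8 and 77.6%, with 4.2 false calls per run. Camera with the preset correlation found a simulated shift of -1.5 in a list of 20 genes in 5 of 5 runs, with 1 other list called over the runs. With an estimated correlation it found the shift in 0 of 5. Genes were simulated as independent of each other. These runs therefore cannot show which setting is right for lists whose members move together between libraries. In simulated libraries with a length trend, the length offset took the gap between long and short genes from 1.88 to 0.05 and the false calls from 47.5 to 6 per run.

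RNA editing, the other subject of the series, cannot be read from counts per gene and was not analysed here. R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.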

Results

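Gene expression from the nuclear, plastid and mitochondrial genomes was measured by sequencing rRNA-depleted total RNA from leaf pieces of Arabidopsis. The series asks how the white leaf margin of the flv/dot4 mutant differs from the green margin of Col-0, and how the margin of Col-0 differs from the leaf centre. There were 2 libraries from each of FLV border, WT border and WT centre. The FLV border libraries held 28674853 and 28610392 counts, the WT border libraries 28532514 and 25257893 and the WT centre libraries 20448315 and 33214552. Mapped reads made up 83.9 and 83.3% of the reads in FLV border, 83.4 and 88.9% in WT border, and 70.9 and 85.6% in WT centre. Library 1 of WT centre stood apart. Small nucleolar and spliceosomal RNAs took 17.1% of its counts (95% Clopper-Pearson interval 17.11 to 17.14%), against 2.16 to 9.92% in the other 5 libraries. The TMM factors were 1.71 and 1.73 in FLV border, 1.22 and 1.14 in WT border, and 0.551 and 0.439 in WT centre.

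DOT4 (AT4G18750) codes for a pentatricopeptide repeat protein needed for the editing of the plastid rpoC1 transcript, and is the gene disrupted in the line. In the TAIR10.1 build it lies on chromosome 4 from 10304662 to 10307673 on the + strand, as 1 exon. DOT4 counts were higher, not lower, in the libraries labelled FLV border: 502 and 616 counts, against 18 and 52 in WT border and 5 and 6 in WT centre. The normalised counts were 10.2 and 12.5 CPM in FLV border, 0.516 and 1.81 in WT border, and 0.444 and 0.412 in WT centre. The log2 fold change of FLV border over WT border was 3.29 ± 0.66 (adjusted p = 0.322 with edgeR), so it was not called. DESeq2 called it at 3.31 with adjusted p = 0.000553, and over all 19 alternatives the adjusted p ranged from 0.000553 to 1. A T-DNA insertion need not remove reads on either side of it, and the counts carry no position within the gene. Of the neighbours on either side, AT4G18740 had 4.96 and 11.6 CPM in FLV border against 4.62 and 7.99 in WT border, and RLP51 had 12 and 6.67 against 2.52 and 3.61.

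The plastid gene rpoC1 (ATCG00180), which codes for a subunit of the plastid-encoded RNA polymerase, is at 20251 to 23084 on the - strand of the plastid genome, in 2 exons. It had 229 and 659 CPM in FLV border, 106 and 203 in WT border, and 286 and 84.1 in WT centre. The log2 fold change was 1.52 ± 0.76 for FLV border over WT border (adjusted p = 0.962, edgeR) and -0.26 ± 0.75 for WT border over WT centre (adjusted p = 0.836). The latter value turned positive with library totals alone, at 0.89, with no filter, at 0.044, without library 1 of WT border, at 0.22, and without library 1 of WT centre, at 0.93. For DOT4 the log2 fold change of WT border over WT centre was 1.43 ± 0.73 (adjusted p = 0.221). With library totals alone it was 2.66 and past the threshold.

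**Figure D1:**
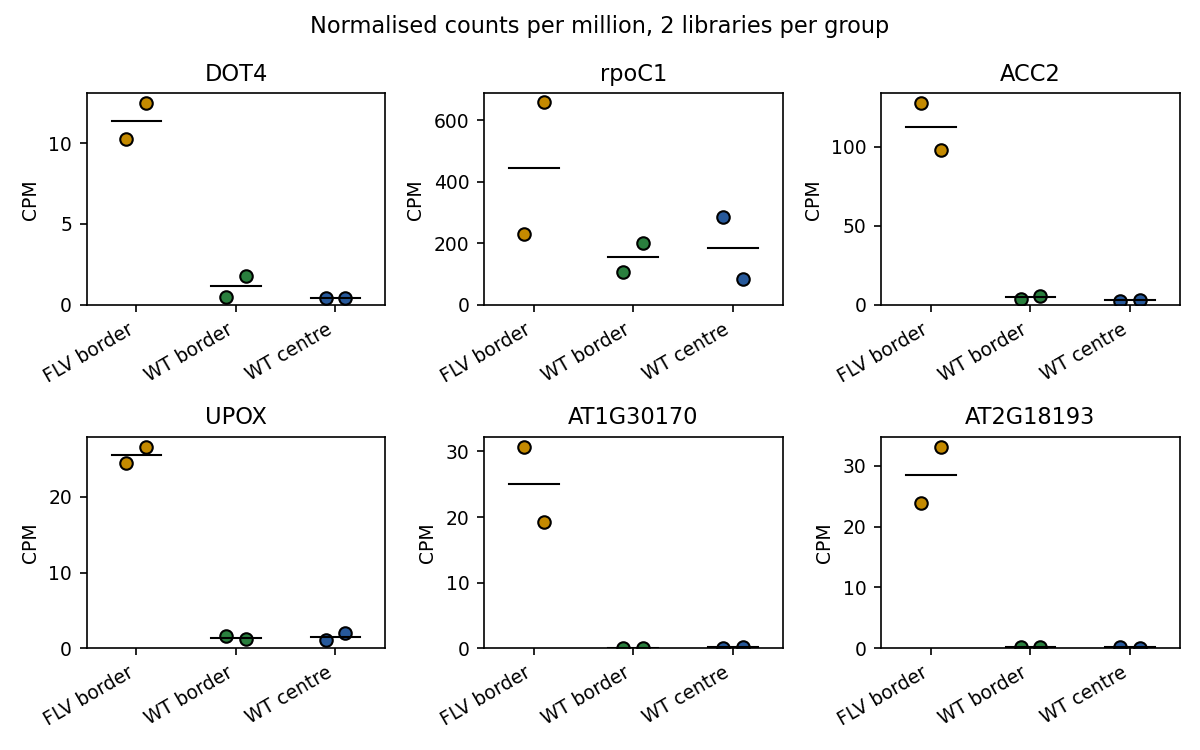
Normalised counts (CPM) of 6 genes, with 1 point per library and a line at the group mean of 2 libraries. DOT4, ACC2, UPOX, AT1G30170 and AT2G18193 are higher in both FLV border libraries than in the other 4, and rpoC1 overlaps between FLV border and WT centre.

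FLV border against WT border asks what differs between the white margin of the mutant and the green margin of Col-0. In the white margin, with the preset correlation, the 28 nuclear photosystem and electron carrier genes fell with a median log2 fold change of -1.95, the 20 light-harvesting complex genes with -2.02 and the 18 Calvin-Benson cycle genes with -1.64. None of the 3 passed with an estimated correlation, with adjusted p of 0.445, 0.632 and 0.296. Nuclear genes induced by mitochondrial dysfunction rose with the preset correlation, with a median of 1.01 (adjusted p = 0.296 with an estimated correlation). Among single genes, edgeR called 12 higher and 1 lower, and 0 with the library number as a block (1313 at an unadjusted p under 0.05), while without the block DESeq2 called 186 and voom 15.

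ACC2, a plastid-targeted acetyl-CoA carboxylase, had 128 and 97.9 CPM in FLV border against 4.04 and 5.59 in WT border (log2 fold change 4.55 ± 0.51, adjusted p = 0.0392). Its neighbour and homologue ACC1, the cytosolic form, had 133 and 121 CPM against 69.8 and 100. UPOX, a mitochondrial protein used as a marker of oxidative stress, rose by 4.17 ± 0.53 and AT1G17960, annotated as a threonyl-tRNA synthetase, by 5.52 ± 0.67. MBP1, a myrosinase-binding protein, rose by 5.35 ± 0.67. AT2G18193, annotated as an ATPase with a P-loop, rose by 6.90 ± 0.64 (adjusted p = 0.0209). The NAC transcription factor gene ANAC087 rose by 5.21 ± 0.64. GMI1, named for its induction by gamma irradiation and mitomycin C, rose by 3.95 ± 0.49. AT5G45990 rose by 5.99 ± 0.72. All of these had an adjusted p of 0.0392 except AT2G18193, and both FLV border libraries were above both WT border libraries for each of the 12 genes called higher.

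Another 3 genes called higher code for proteins with a DUF295 domain. AT1G30170 had 30.7 and 19.3 CPM in FLV border and 0.0287 and 0 in WT border (fitted log2 fold change 10.32 ± 0.91, adjusted p = 0.0209). The WT border libraries held 1 count, and the ratio of the summed counts was 1587, with a counting interval of 285 to 62720. The tandem genes AT5G53230 and AT5G53240 rose by 7.06 ± 0.80 and 6.89 ± 0.81 (adjusted p = 0.0392), and as near-identical neighbours they can share reads. AT5G03495 rested on 3 counts in WT border, with a ratio of 156 and a counting interval of 53.2 to 758 (adjusted p = 0.0392). The single gene called lower was AT4G13575, of unknown function, with 0.163 and 0.182 CPM against 8.08 and 14.6 (-6.00 ± 0.62, adjusted p = 0.0316). ACC2, ANAC087, GMI1, AT5G45990 and AT5G03495 were chosen after their values were seen, since the naming rule leaves them out.

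These calls come from 21852 tested genes, of which 1209 had an unadjusted p under 0.05. With no difference in any gene, a share of 0.05 of the tested genes would have such a p. This count and those given for other fits of this comparison therefore do not by themselves show further changed genes. No gene of the organelles was called: 9 plastid and 18 mitochondrial genes had an unadjusted p under 0.05 in edgeR, DESeq2 called 2 of each, and voom called 0 of each. The composition of the libraries differed along with the group: small nucleolar and spliceosomal RNAs took 9.92% (95% Clopper-Pearson interval 9.906 to 9.928%) and 6.07% (6.061 to 6.079%) of the counts in FLV border, against 4.55% (4.546 to 4.561%) and 3.38% (3.374 to 3.388%) in WT border, and rRNA loci, left out of the fit, held 142 and 149 per 1e6 counts against 0.456 and 9.26. The FLV border and WT border libraries did not overlap in 38% of the genes (8297), where chance gives 33.3%. With the length offset only AT1G30170 and AT2G18193 were called. The fold changes of the other 11 moved little (4.55 to 4.49 for ACC2, 4.17 to 4.35 for UPOX). UPOX then stood at adjusted p = 0.0505, and over its 19 alternatives the adjusted p ranged from 3.6e-10 to 0.661. The 13 genes kept their sign in every fit that leaves out 1 library, and over all alternatives the log2 fold change of AT2G18193 lay between 6.65 and 7.44 and that of AT1G17960 between 5.10 and 6.14, while the calls themselves changed. With edgeR, 0 genes were called without library 1 of FLV border (503 at unadjusted p under 0.05), 1 without library 2 of FLV border (AT1G30170), 0 without library 1 of WT border (766) and 0 without library 2 of WT border (1099). Without library 1 of WT centre 29 genes were called and without library 2 of WT centre 22, in both cases with all 13 among them.

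Every tested member of the light-harvesting list (20), the nuclear photosystem list (28), the Calvin-Benson list (18), the chlorophyll synthesis list (23) and the list of nuclear genes for plastid ribosomal proteins (30) had a negative log2 fold change. So did all 27 plastid genes for photosystems, cytochrome b6f and the Rubisco large subunit. Both FLV border libraries were below both WT border libraries for 28 of 28 nuclear photosystem and 18 of 18 Calvin-Benson genes but for 11 of 20 light-harvesting genes, where chance gives no overlap in either direction for 33.3%. The camera adjusted p was 3.7e-10 for light harvesting for 20 genes, with LHCA6 at -2.06 ± 0.75. It was 4.3e-30 for the nuclear photosystem list, with PSAD-2 at -4.00 ± 1.14, PSAG at -2.43 ± 0.70 and plastocyanin gene PETE1 at -2.34 ± 0.72. It was 6.6e-20 for the Calvin-Benson list, with the Rubisco small subunit gene RBCS2B at -2.96 ± 0.75 and sedoheptulose-bisphosphatase gene SBPASE at -1.67 ± 0.52. The chlorophyll synthesis list fell with a median of -0.88 (adjusted p = 2.8e-09), with PORB at -1.99 ± 0.85 and PORC at -1.24 ± 0.51. The nuclear plastid ribosome list fell with a median of -0.98 (adjusted p = 3.6e-13), with PRPL35 at -1.38 ± 0.53. The plastid-encoded photosynthesis list fell with a median of -1.24 (adjusted p = 9.9e-14), with petN at -2.37 ± 0.59, from 180 and 143 CPM in WT border to 21.1 and 41.4. The adjusted p with an estimated correlation was 0.632 for light harvesting, 0.296 for the Calvin-Benson list and 0.445 for the nuclear photosystem, chlorophyll, nuclear plastid ribosome and plastid photosynthesis lists. Over 15 other alternatives with the preset correlation the adjusted p ranged from 5.6e-23 to 0.0023 for light harvesting, 4.5e-44 to 1.2e-16 for the nuclear photosystem list and 6.2e-24 to 1.5e-12 for the Calvin-Benson list. Light harvesting had a median of -3.63 without library 2 of FLV border and -0.80 without library 2 of WT border, and plastid photosynthesis had -1.92 without library 2 of FLV border.

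Of the 6 plastid ATP synthase and 12 plastid ndh genes, 0 had an unadjusted p under 0.05 in edgeR, and 6 and 11 had a negative fold change. As lists they fell with the preset correlation, with medians of -0.67 (adjusted p = 0.0101) and -0.56 (adjusted p = 0.0209). Their adjusted p was 0.632 and 0.797 with an estimated correlation, and ranged from 7.2e-05 to 0.446 and from 2.4e-06 to 0.914 over 15 other alternatives. For the ATP synthase list the median was -0.21 without library 1 of FLV border and -0.33 without library 2 of WT border, neither called, and -1.62 without library 2 of FLV border. For the ndh list it was -0.07 without library 1 of FLV border and -0.19 without library 2 of WT border, neither called, -1.44 without library 2 of FLV border and -0.85 without library 1 of WT border. The length offset also ended the ndh call, at -0.50. The 13 genes of the type mostly transcribed by the nuclear-encoded polymerase had a median of 0.58 (adjusted p = 0.175), with rpoC2 at 1.21 ± 0.62. They passed without library 1 of FLV border, at 0.93. The 19 other plastid-encoded ribosomal protein genes had a median of 0.14 (adjusted p = 0.723). That list passed upward without library 1 of FLV border, at 0.56, and downward without library 2 of FLV border, at -0.55. The nuclear genes for plastid transcription had a median of -0.06 (adjusted p = 0.236), with TRXZ at -1.32 ± 0.57 and SIG4 at -1.21 ± 0.57, and passed without library 2 of FLV border, at -0.67. Plastid chaperone genes had a median of -0.41 (adjusted p = 0.0826). They passed without library 2 of FLV border, at -0.66, and without library 2 of WT border, at -0.63. The 6 greening regulators had a median of -0.02 (adjusted p = 0.602), with the transcription factor gene GLK1 at -2.20 ± 0.76 (39.4 and 40.8 CPM against 193 and 174, adjusted p = 0.757).

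All 14 mitochondrial genes for cytochrome c maturation, ribosomal proteins and related functions were higher (median 0.96, adjusted p = 1.4e-08), with ccb203 at 2.60 ± 0.52 and ccb382 at 1.51 ± 0.46. Of the 24 gene models for the respiratory chain and ATP synthase, 20 were higher and the list rose (median 0.56, adjusted p = 0.0045), with nad7 at 1.25 ± 0.58. These models include several parts each of nad1, nad2 and nad5 and copies of atp6, so some genes count more than once. The nuclear genes induced by mitochondrial dysfunction rose (median 1.01, adjusted p = 8.9e-06), 9 of 12 with a positive fold change. Both FLV border libraries were above both WT border libraries for 5 of the 12 and below them for 3. UPOX was called, the alternative NAD(P)H dehydrogenase gene NDB4 had 4.71 ± 0.78 (adjusted p = 0.15) and the alternative oxidase gene AOX1A 1.38 ± 0.43 (40 and 48.5 CPM against 16.2 and 17.8, adjusted p = 0.641). The adjusted p was 0.445, 0.632 and 0.296 for the 3 lists with an estimated correlation. Over 15 other alternatives it ranged from 9.0e-10 to 4.7e-05, from 0.00079 to 0.0586 and from 3.8e-07 to 0.00037. The respiratory list was not called without library 2 of FLV border, at 0.37, and stood at 0.37 without library 1 of WT border. The list of mitochondrial dysfunction had 0.66 without library 1 of FLV border.

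The remaining lists did not pass in FLV border against WT border. Sugar starvation genes had a median of -0.45 (adjusted p = 0.175), leaf margin genes -0.42 (0.228), phloem markers -0.43 (0.175), guard cell markers -0.34 (0.658) and DNA replication genes -0.45 (0.236). Xylem markers had -0.06 (0.877), trichome regulators 0.29 (0.787), epidermis genes 0.48 (0.162), mitosis genes -0.15 (0.843) and anthocyanin genes 0.76 (0.602). Jasmonate genes had -0.35 (0.638), salicylate genes 0.07 (0.741) and glucosinolate genes -0.32 (0.638). The test leaned downward for the xylem list, with a mean of 0.02, and for the salicylate list, with a mean of 0.10. Without library 1 of FLV border, anthocyanin passed downward at -0.75, jasmonate at -0.96 and salicylate at -0.65, and without library 2 of FLV border anthocyanin passed upward at 1.33 and epidermis at 0.55. Without library 1 of WT border, anthocyanin passed at 1.52, epidermis at 0.42, mitosis at 0.71, phloem at -0.68 and sugar starvation at -0.72, and without library 2 of WT border jasmonate passed at -0.74 and mitosis at -0.70. Of 450 distinct list members tested, edgeR called only UPOX, 67 had an unadjusted p under 0.05, DESeq2 called 4 higher and 6 lower and voom 1. Adjusted over the list alone, 4 Calvin-Benson genes were lower, and 3 genes of mitochondrial dysfunction, ccb203 and the vegetative storage protein gene VSP1 (4.47 ± 1.02) were higher.

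**Figure D2:**
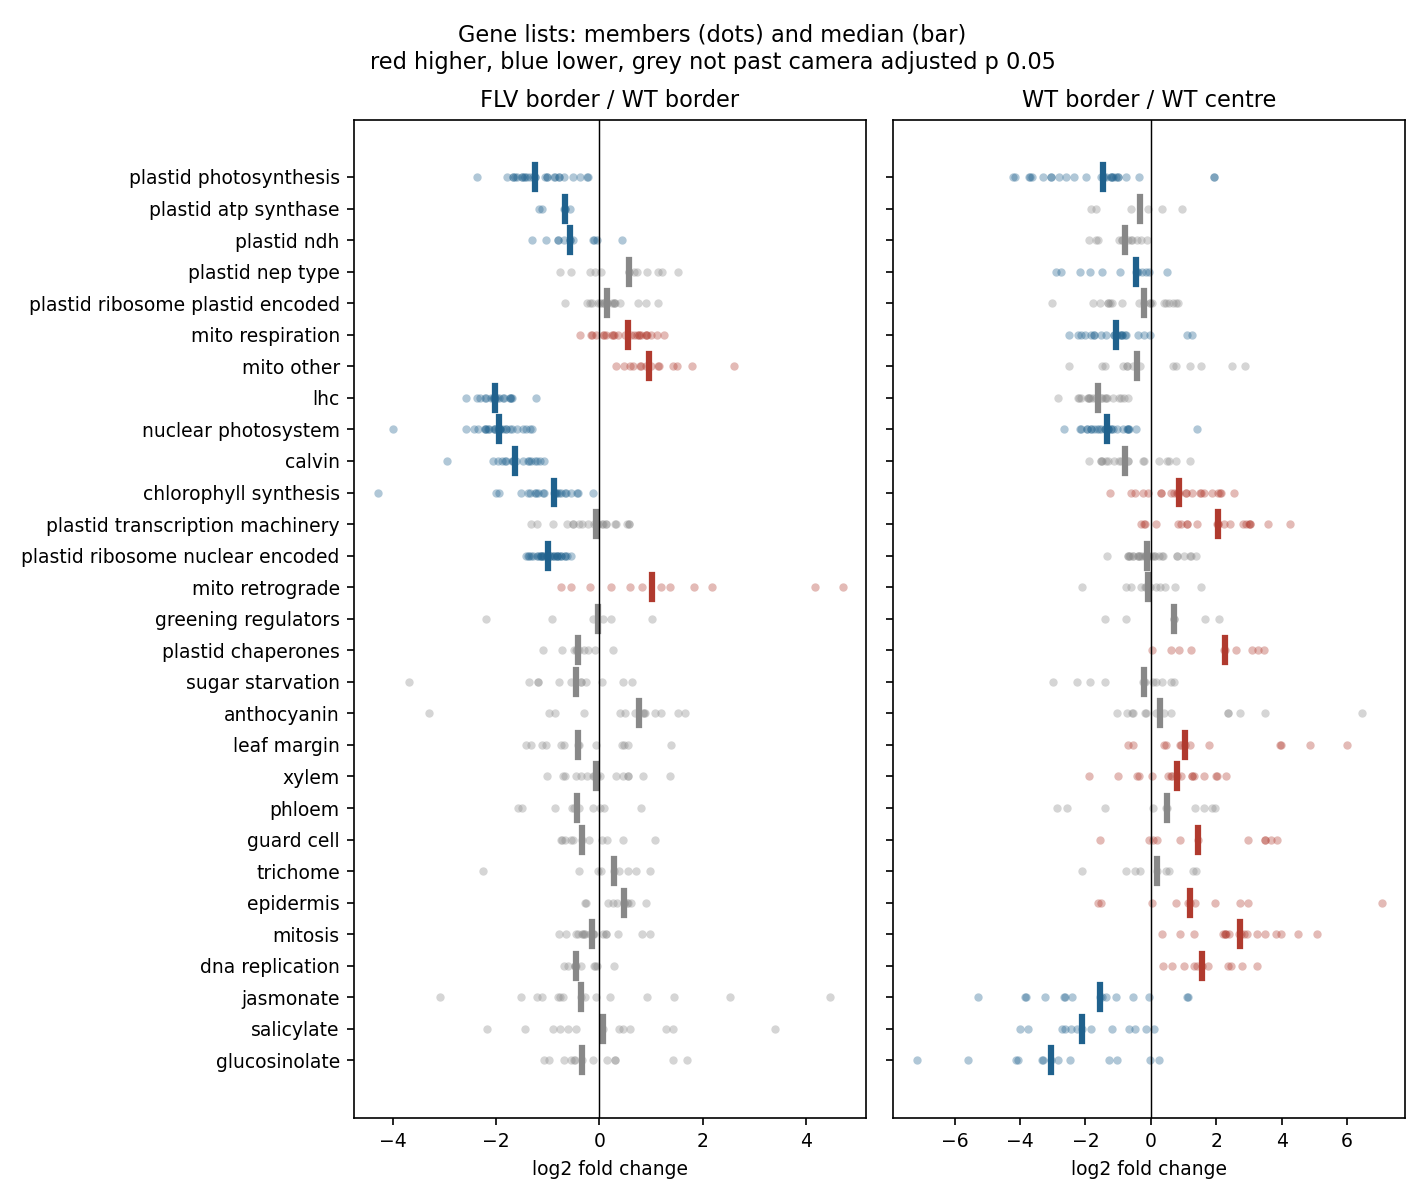
Log2 fold change of the members (dots) of each gene list and the list median (bar), for FLV border over WT border on the left and WT border over WT centre on the right. Red and blue mark lists that passed camera upward and downward and grey marks the others; 11 lists passed on the left and 16 on the right, and none of either with an estimated correlation, and the 3 right-hand lists of nuclear photosystem, nuclear-encoded polymerase and mitochondrial respiratory genes have medians above 0 with library totals and no TMM, which raises the median gene by 1.25.

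WT border against WT centre asks how the green margin of a Col-0 leaf differs from its middle. With the preset correlation, lists of cell division, epidermis, stomatal lineage, plastid chaperone and plastid transcription genes were higher in the margin. None of them passed with an estimated correlation (adjusted p from 0.409 to 0.467), and the epidermis list also lost its call with the length offset, at 0.51. The other lists kept theirs, but the offset took the median from 2.05 to 1.15 for plastid transcription and from 2.25 to 1.52 for chaperones. For DNA replication the median went from 1.56 to 0.95, while mitosis stayed at 2.72. With the offset 0 single genes of the mitosis, DNA replication, plastid transcription, chaperone and stomatal lineage lists were called. In the epidermis list 1 was. Glucosinolate, salicylate and jasmonate lists were higher in the centre with the preset correlation, and had adjusted p of 0.409, 0.409 and 0.616 with an estimated one. The jasmonate list was also not called without library 2 of WT border, at -0.70, or library 1 of WT centre, at -0.39. The 18 mitosis genes were all higher in the border, with a median log2 fold change of 2.73, and the 13 glucosinolate genes had a median of -3.06. In total 683 genes were called higher in the border and 656 lower.

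PDF1, an epidermal marker, had 60.9 and 20 CPM in the border against 0.0888 and 0.481 in the centre (7.06 ± 0.92, adjusted p = 0.0262). SDD1, a subtilisin-like protease that limits stomatal density, rose by 5.98 ± 0.60, the chitinase family gene AT2G43590 by 6.59 ± 0.85, AT3G16660, annotated with a pollen allergen and extensin domain, by 6.27 ± 0.80 and the E6-like gene AT2G33850 by 6.14 ± 0.80 (each adjusted p = 0.0262). CYP77B1, a cytochrome P450, had 26.6 and 2.92 CPM against 0.178 and 0, a ratio of summed counts of 205 with a counting interval of 56.6 to 1695 (adjusted p = 0.0336). The largest differences downward included BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis (-7.17 ± 0.91), and AT1G49500 (-6.36 ± 0.77, both adjusted p = 0.0262). IGMT2, an O-methyltransferase of indole glucosinolates, had -5.96 ± 1.09 (adjusted p = 0.0313). EXT4, an extensin, had -6.27 ± 1.35 and AT1G76800, of the vacuolar iron transporter family, -6.47 (both adjusted p = 0.0393), and AT1G66850 had -6.32 ± 1.39 (adjusted p = 0.0408). Without library 1 of WT centre the fitted value was 12.05 for CYP77B1, -2.26 for AT1G66850 and -3.00 for EXT4, and without library 2 of WT centre it was -2.86 for AT1G76800, none of them called.

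Mitosis genes rose as a list (adjusted p = 8.0e-09), with the cytokinesis syntaxin gene KNOLLE at 5.10 ± 0.81, CDC20.1 at 4.49 ± 0.73 and the kinase gene CDKB2;1 at 3.98 ± 0.70. Of the 18, 6 were called and 15 passed adjusted over the list alone. All 11 DNA replication genes were higher (median 1.56, adjusted p = 4.6e-05), with PCNA2 at 2.78 ± 0.60 and MCM7 at 2.45 ± 0.45; 4 were called and 7 passed adjusted over the list alone. Guard cell and stomatal lineage markers rose (median 1.45, adjusted p = 0.0039), with TMM at 2.97 ± 0.50 and SPCH at 3.48 ± 0.68, and 3 called, or 5 adjusted over the list alone. MUTE rested on 3 counts in the centre, with a ratio of 11.6 and a counting interval of 3.85 to 57.5. Epidermis genes rose (median 1.19, adjusted p = 0.0054), with ATML1 at 2.98 ± 0.50 and LACS2 at 2.72 ± 0.55, while CER6 had -1.52 ± 0.47. In that list 3 were called, and 3 higher and 2 lower adjusted over the list alone. Leaf margin and auxin genes rose (median 1.04, adjusted p = 0.0046), with the auxin synthesis genes TAA1 at 3.99 ± 0.77 and YUC2 at 3.97 ± 0.78. WOX1 rested on 2 counts in the centre, with a ratio of 31.4 and an interval of 8.56 to 262. In that list 3 were called, or 4 adjusted over the list alone. Xylem markers rose (median 0.80, adjusted p = 0.036), with the cellulose synthase gene CESA4 at 2.31 ± 0.46 as the 1 called, also adjusted over the list alone. Phloem markers did not pass (median 0.48, adjusted p = 0.459), with SEOR2 called at 1.95 ± 0.46, SWEET11 at -2.57 ± 0.80 and 4 higher and 3 lower adjusted over the list alone. Trichome regulators had 0.18 (adjusted p = 0.837). The adjusted p was 0.467 for mitosis with an estimated correlation, and 0.409 for DNA replication, guard cell, epidermis, leaf margin and xylem. Over 15 other alternatives it ranged from 5.6e-18 to 5.7e-06 for mitosis, 3.5e-07 to 0.0013 for DNA replication, 0.00013 to 0.0322 for guard cell, 0.00027 to 0.0954 for epidermis, 0.0013 to 0.12 for leaf margin and 0.0029 to 0.0954 for xylem. The leaf margin list was not called without library 1 of WT border, at 0.72, or library 2 of WT centre, at 0.92. The xylem list was not called without library 2 of WT border, at 0.75, or library 2 of WT centre, at 0.93, and stood at 0.53 without library 1 of WT centre. Guard cell markers stood at 0.95 without library 2 of WT border.

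The plastid transcription machinery rose (median 2.05, adjusted p = 7.2e-08), with FLN1 at 4.26 ± 0.64, PTAC10 at 3.60 ± 0.68 and the sigma factor gene SIG2 at 3.02 ± 0.51, and 8 of 21 called, or 12 adjusted over the list alone. All 10 plastid chaperone genes were higher (median 2.25, adjusted p = 1.7e-05), with CPN60B1 at 3.45 ± 0.59 (397 and 421 CPM against 42.9 and 31.8) and CPN60A at 3.10 ± 0.59; 3 were called, or 7 adjusted over the list alone. Chlorophyll synthesis genes rose (median 0.87, adjusted p = 0.0054), 18 of 23 with a positive fold change, with DVR called at 2.14 ± 0.48, also adjusted over the list alone. The greening regulators did not pass (median 0.71, adjusted p = 0.353), with GUN1, a gene of plastid-to-nucleus signalling, called at 2.08 ± 0.49, also adjusted over the list alone. Nuclear genes for plastid ribosomal proteins had a median of -0.13, a mean of -0.002 and a test that leaned upward (adjusted p = 0.968), and passed upward with the length offset, at 0.27. The adjusted p was 0.409 for the transcription machinery and the chaperones with an estimated correlation, and 0.684 for chlorophyll synthesis. Over 15 other alternatives it ranged from 1.4e-11 to 1.6e-05, from 1.0e-06 to 0.00084 and from 8.0e-05 to 0.114. The chlorophyll synthesis list was not called without library 1 of WT centre, at 0.81, and stood at 1.48 without library 2 of WT centre.

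The plastid photosynthesis genes fell (median -1.47, adjusted p = 2.3e-07), with psbM at -3.74 ± 0.67, psaI at -4.22 ± 0.86, petL at -3.31 ± 0.73 and petG at -3.63 ± 0.81; 7 of 27 were called, or 11 adjusted over the list alone. The nuclear photosystem genes fell (median -1.35, adjusted p = 0.00085; median 0.005 with library totals and no TMM), with PSBTN at -2.64 ± 0.73. The genes transcribed by the nuclear-encoded polymerase fell (median -0.45, adjusted p = 0.0451; median 0.76 with library totals and no TMM), with rpl33 called at -2.75 ± 0.59, and 2 adjusted over the list alone. Light-harvesting genes did not pass (median -1.61, adjusted p = 0.0939), although all 20 were negative. Calvin-Benson genes had -0.81 (adjusted p = 0.131), plastid ATP synthase genes -0.35 (0.556), ndh genes -0.80 (0.131) and the other plastid-encoded ribosomal protein genes -0.22 (0.404). The adjusted p was 0.467 for plastid photosynthesis with an estimated correlation, 0.794 for the nuclear photosystem list and 0.85 for the genes of the nuclear-encoded polymerase. Over 15 other alternatives it ranged from 1.3e-07 to 0.139, from 1.2e-10 to 0.81 and from 0.0012 to 0.625. No nuclear photosystem gene was called by edgeR: 7 had an unadjusted p under 0.05, DESeq2 called 1 higher and 6 lower and voom 1 lower. The 14 plastid genes called, all lower, were 71 to 201 bases long. The length offset took the median of plastid photosynthesis to -0.83, of the nuclear photosystem list to -0.92 and of the genes of the nuclear-encoded polymerase to -1.10, and ended the 3 calls. Without library 1 of WT centre, psaI stood at -2.55, and petL at -2.17 and petG at -1.95 were not called. The nuclear photosystem list was not called without library 2 of WT centre, at -0.18. The genes of the nuclear-encoded polymerase were not called without library 1 of FLV border (-0.38), library 2 of FLV border (-0.38), library 1 of WT border (-0.40), library 2 of WT border (-0.71) or library 1 of WT centre (0.12), and stood at -0.87 without library 2 of WT centre. Their call also ended with the library number as a block (-0.43) and with no filter (-0.15). Light-harvesting genes passed downward with the library number as a block (-0.90) and with library totals and no TMM (-0.24). They passed downward without library 2 of WT border (-3.06) or library 1 of WT centre (-2.47) and upward without library 2 of WT centre (1.61). Calvin-Benson genes passed without library 1 of WT centre (-0.95), and without library 2 of WT centre the ndh genes (-1.39) and the plastid-encoded ribosomal protein genes (-0.53) passed. The latter passed upward instead with the length offset (0.41) and with the length and GC offset (0.35).

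Among mitochondrial genes, the respiratory list fell (median -1.05, adjusted p = 0.001; median 0.23 with library totals and no TMM), 22 of 24 with a negative fold change, with nad4L at -2.02 ± 0.53. With an estimated correlation the adjusted p was 0.577, and it ranged from 7.8e-05 to 0.575 over 15 other alternatives. None of its genes was called by edgeR, with 9 at an unadjusted p under 0.05, DESeq2 calling 1 higher and 8 lower and voom 0. The length offset ended the call at -0.41, and without library 1 of WT centre the median was -0.55. The other mitochondrial genes went both ways, with a median of -0.44, a mean of 0.07 and a test that leaned upward (adjusted p = 0.706). Of them rps3 was called at 2.86 ± 0.51 and rpl5 at 2.48 ± 0.53; adjusted over the list alone 3 were higher and 2 lower. Nuclear genes induced by mitochondrial dysfunction had a median of -0.09 (adjusted p = 0.968).

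Aliphatic glucosinolate synthesis genes fell in the border (adjusted p = 2.0e-08), 12 of 13 with a negative fold change, with CYP79F1 at -5.60 ± 0.83, MAM1 at -4.13 ± 0.67 and CYP83A1 at -2.84 ± 0.49 (34.4 and 24.1 CPM against 179 and 240). In that list 8 were called, or 10 adjusted over the list alone. Salicylate genes fell (median -2.11, adjusted p = 0.00085), with PR1 at -3.99 ± 0.85 as the 1 called, or 5 adjusted over the list alone. Jasmonate genes fell (median -1.57, adjusted p = 0.0046), with the allene oxide synthase gene AOS at -3.25 ± 0.65 and the cyclase gene AOC2 at -2.67 ± 0.59 called, or 5 adjusted over the list alone. With an estimated correlation the adjusted p was 0.409 for glucosinolate and salicylate genes and 0.616 for jasmonate genes. Over 15 other alternatives it ranged from 1.3e-10 to 4.8e-06, from 0.00036 to 0.0129 and from 1.8e-05 to 0.207. The jasmonate list lost its call without library 2 of WT border (-0.70) or library 1 of WT centre (-0.39), and stood at -3.05 without library 1 of WT border. The salicylate list stood at -1.32 without library 1 of WT centre. Sugar starvation genes had -0.21 (adjusted p = 0.474) and anthocyanin genes 0.28 (0.353). Without library 2 of WT border they passed, at -1.11 and 0.83.

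The 1339 called genes were 1318 nuclear, 14 plastid and 7 mitochondrial, and 6532 of 21852 genes had an unadjusted p under 0.05. The libraries of the groups did not overlap in 57.8% of the genes, where chance gives 33.3%. Fold changes followed gene length in this comparison. The median log2 fold change rose from -0.88 in the shortest decile of nuclear protein-coding genes to 0.79 in the longest, and library 1 of WT centre held the most small nucleolar RNA. After the length offset 61 genes were called, all of them among the 1339. All 1339 kept their sign, and 6030 genes had an unadjusted p under 0.05 in edgeR with the offset. The smallest adjusted p of edgeR moved from 0.0262 to 0.0485, close to the threshold. The fall to 61 calls therefore does not measure how many calls rested on length. With the offset 12 lists passed, 10 of the 16 called before in the same direction and the 2 plastid ribosome lists, upward. The epidermis list, at 0.51, and the xylem list, at 0.68, also lost their call. Without library 1 of WT border 1 gene was called (AT3G16660), without library 2 of WT border 13, without library 1 of FLV border 203, without library 2 of FLV border 298 and without library 2 of WT centre 3260. With library totals and no TMM the median change per gene was 1.25, and 7448 genes were called higher and 350 lower. The 3 lists whose median turned positive with it stayed below the median of all genes in that setting, 1.24. In FLV border against WT border the same choice gave a median change per gene of 0.54 and kept 13 of the 13 calls.

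**Figure D3:**
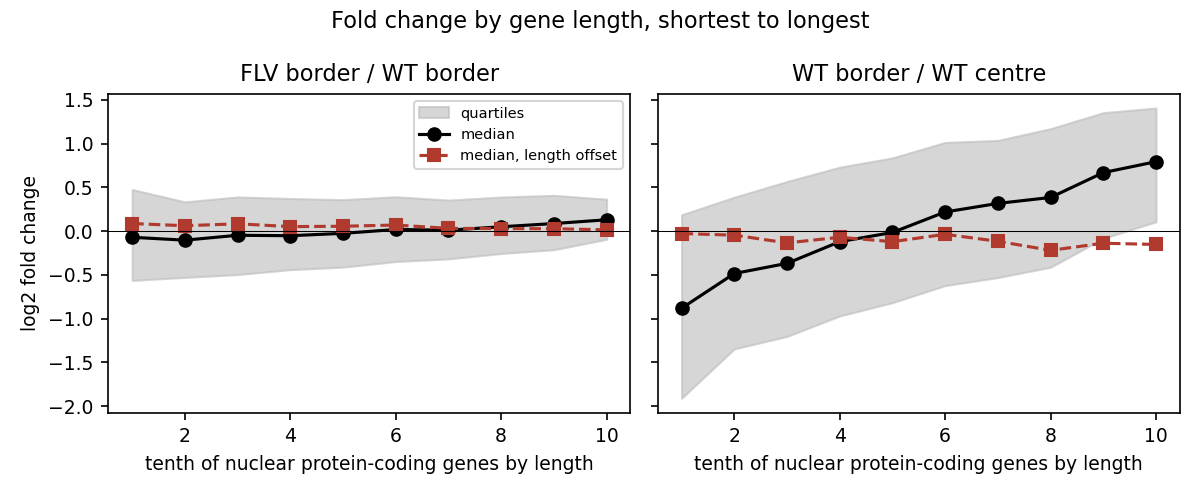
Median log2 fold change (black) and quartiles (grey) of nuclear protein-coding genes in 10 equal groups by gene length, from shortest to longest, with the median after the length offset in red. The medians of the border to centre comparison on the right run from -0.88 in the shortest group to 0.79 in the longest, and those of FLV border to WT border on the left lie between -0.10 and 0.13.

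Plastid genes took 18.5% ± 8.07 (SD, n = 2) of the counts in FLV border, 27.8% ± 5.14 in WT border and 40.2% ± 2.44 in WT centre. Mitochondrial genes took 2.13% ± 0.134 in FLV border, 0.989% ± 0.0358 in WT border and 0.952% ± 0.56 in WT centre. Nuclear genes took 79.3% ± 8.2, 71.2% ± 5.18 and 58.9% ± 3. In single libraries the plastid share was 12.8% (95% Clopper-Pearson interval 12.82 to 12.84%) and 24.2% (24.23 to 24.26%) in FLV border, and 24.2% (24.15 to 24.18%) and 31.4% (31.42 to 31.46%) in WT border. The plastid shares of the 2 border groups overlapped, while the mitochondrial share was higher in both FLV border libraries by more than the spread of either border group. These shares were not tested.

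**Figure D4:**
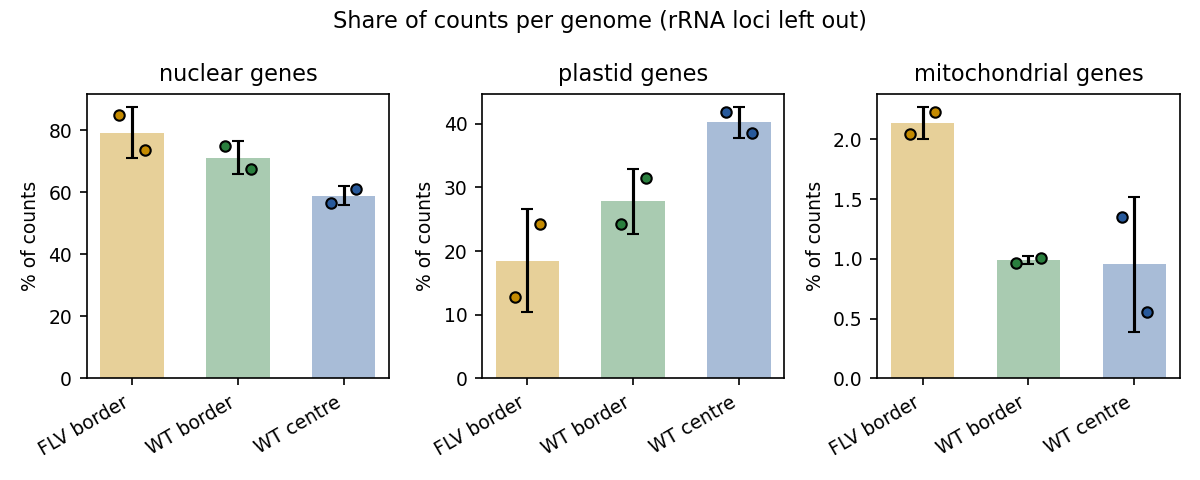
Share of counts from nuclear, plastid and mitochondrial genes in percent, with 1 point per library and bars at the mean with the standard deviation of 2 libraries. The mitochondrial share of both FLV border libraries lies above that of the other 4, and the plastid share is highest in WT centre.

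The 2 comparisons share the WT border libraries, with opposite sign. Across 21852 genes, which are not independent replicates, the log2 fold changes of FLV border over WT border and of WT border over WT centre had a Pearson correlation of -0.105 and a Spearman correlation of -0.047. Simulated libraries with no group effect and the same shared controls gave a mean of -0.482 for Pearson, from -0.493 to -0.472, and -0.468 for Spearman. With real differences in the data the correlation also shrinks because the fold changes spread wider, so the covariance was compared as well. It was -0.134, against -0.263 in the simulations, from -0.271 to -0.258. Of the genes called, 2 were called in both comparisons. AT4G13575 was lower in FLV border (-6.00) and lower in WT border than in the centre (-2.08), and AT5G03495 was higher in FLV border (7.16) and lower in the border than in the centre (-5.09). Simulations with shared controls and no group effect gave a mean of 0 genes in the direction of the former and 0.15 (0 to 2) in that of the latter, which rests on 3 counts in the shared WT border libraries. Few genes are called without a group effect, so these simulations are no measure for the overlap. From the numbers of called genes alone, 0.03 and 0.36 genes would be called in both if the comparisons were independent, which the shared controls prevent. Both genes are outside the naming rule for the second comparison and were chosen after their values were seen. The Spearman value turned positive, at 0.038, without library 1 of FLV border, and was -0.107 without library 2 of FLV border, -0.213 without library 1 of WT border, -0.233 without library 2 of WT border, -0.032 without library 1 of WT centre and -0.091 without library 2 of WT centre. The values that shared controls alone would give in these smaller sets were not simulated. None of the genes was called in both without any one of the 4 border libraries, and 6 were without either WT centre library.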

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

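Of the tests below, those of the length offset on the 3 lists and on DOT4, that of exchanged labels and that of clock genes in the same direction were chosen only after the result was seen. Counts at the rRNA loci, which the comparisons leave out, averaged 145 per 1e6 counts in the FLV border libraries (142, interval 138 to 146, and 149, interval 144 to 153), against 0.456 and 9.26 in WT border and 1.37 and 0.331 in WT centre.

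Fold changes of WT border over WT centre followed gene length, with a gap of 1.68 in median log2 fold change between the longest and shortest nuclear protein-coding genes. Thinning the border libraries to the effective depth of the centre libraries left a gap of 1.69. Such thinning keeps each gene's expected share of the counts and could hardly change the gap, so it cannot decide about depth. Library 1 of WT centre alone is argued against, since the gap was 1.76 without it and 1.36 without library 2. Length as the whole cause of the list results is argued against for mitosis, with a median of 2.73 before the length offset and 2.72 after (SD of members 1.24), and for glucosinolate genes (-3.06 and -3.29, SD 2.15). Their median lengths were 1548.5 and 1595 bases, and the deciles at 1440 and 1620 bases had medians of -0.015 and 0.219. The offset could thus move these lists little, and they say nothing about lists of longer genes. Outside this test, it took plastid chaperones from 2.25 to 1.52, plastid transcription from 2.05 to 1.15 and DNA replication from 1.56 to 0.95. For plastid photosynthesis genes the offset left -0.83 of -1.47 (SD 1.11) and ended the call, so length and tissue cannot be told apart for this list, whose members have a median length of 189 bases. RNA quality, library preparation and the tissue itself were not tested, and each may add to the trend.

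DOT4 counts were higher in the libraries labelled FLV border than in all 4 others. An exchange of labels between the FLV border and WT border libraries is argued against by the nuclear photosystem genes, 28 of 28 lower in the libraries labelled FLV border with a median of -1.95 (SD 0.503). A length trend is argued against by its size, since the medians of the length deciles lay between -0.10 and 0.13 in this comparison. The length offset could thus move DOT4 little, and left 3.26 ± 0.61 of 3.29. Transcription that starts in the T-DNA, or feedback on a promoter left intact, may raise such counts. Neither was tested, because counts per gene carry no position.

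Light-harvesting transcripts were lower in library 1 than in library 2 of every group, by a mean log2 of 2.32 in FLV border, 2.06 in WT border and 4.46 in WT centre (19, 17 and 20 of 20 members). Gene length is argued against, as the length offset left from 0.952 to 1.104 of the difference. A shared time of harvest by library number may be the cause: morning minus evening clock genes differed between the libraries in the same direction in 3 of 3 groups, by 4.28, 3.299 and a small 0.13 in WT centre, where chance alone gives that in 1 of 4 cases. Of 10 clock genes 9 differed in the same direction in all groups, against 30.4% of all tested genes (exact binomial p = 0.000163, genes not independent). TOC1 had 66.1 and 20.3 CPM in FLV border, 58.4 and 19.3 in WT border and 34.6 and 16.6 in WT centre. GI and PRR5, counted with TOC1 as evening genes, rose from library 1 to library 2 instead. GI had 19.5 and 45.9, 10.6 and 69.5, and 6.84 and 33.1 CPM in these groups. PRR5 had 13.9 and 31.1, 17.7 and 29.2, and 7.64 and 36.8. Their rise makes the morning minus evening difference smaller. Whether it goes with or against a difference in time was not tested. The light-harvesting difference was largest in WT centre (4.46), where the morning minus evening difference was smallest (0.13). There the morning gene RVE1 fell from 11 to 1.99 CPM, while CCA1, LHY and PRR9, the other morning genes, rose. The 0.13 is thus a balance of opposite changes and does not show that clock genes differed little in WT centre. Whether light-harvesting and clock genes went together across the groups stays open. The labels give no time or batch, so other differences between the libraries stay open. A shared time would widen the spread within groups, and would favour no group only if its effect were equal in all of them.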

How the results depend on the processing

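The length offset, the length and GC offset and the fit of nuclear protein-coding genes alone were chosen after seeing the data. Where a value changed and no other cause is named, the cause was not tested. Without 1 library, the lone library of its group is assumed to vary like the others. In FLV border against WT border the count of 13 genes stayed between 13 and 18 with RLE scaling, scaling from nuclear genes, library totals, rRNA loci kept, only the 4 libraries compared, robust=FALSE, nuclear protein-coding genes and voom. It was 23 with no filter, 186 with DESeq2, 2 with the length offset, 2 with the length and GC offset and 0 with the library number as a block (1313 at unadjusted p under 0.05 in edgeR). Replicate deviations correlated at 0.366 between FLV border and WT border, 0.047 between FLV border and WT centre and 0.082 between WT border and WT centre. The main fit with no block was fixed beforehand, and the 0.366 leaves an effect shared by library number open in this comparison. Without 1 library the count was 0 to 29. The median change per gene was 0.54 with library totals. DOT4 was 3.31 with DESeq2 and past the threshold, and 2.65 to 4.43 without 1 library. Where 11 lists passed, 0 did with an estimated correlation, 0 with fry and 2 with mixed fry. Without 1 library 11 to 16 lists passed in all, and of the 11, 9 kept their call without library 1 of FLV border or library 2 of WT border, 10 without library 2 of FLV border and 11 without any one of the others. MCM7 turned to 0.076 with library totals. Without 1 library, values spanned 0 for rps2 (-0.16 to 1.28), PCNA2 (-1.10 to 0.15), DIN6 (-4.66 to 0.73), and the lists of plastid-encoded ribosomal proteins (-0.55 to 0.56), anthocyanin (-0.75 to 1.52), salicylate (-0.65 to 0.44) and mitosis (-0.70 to 0.71).

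In WT border against WT centre the count of 1339 genes was 7798 with library totals, 2055 with no filter, 337 with only the 4 libraries, 61 with the length offset, 81 with the length and GC offset, 4358 with DESeq2 and 858 with voom, and 1 to 3260 without 1 library. It stayed between 1080 and 1395 with the 6 others. The median change per gene tested in both settings was 1.25 with library totals, 0.27 with no filter, -0.18 with either offset and 0.17 with DESeq2. DOT4 was 2.66 with library totals, and rpoC1 was 0.89 with library totals, 0.044 with no filter and -0.80 to 0.93 without 1 library. Where 16 lists passed, 0 did with an estimated correlation, 3 with fry and 12 with mixed fry. Without 1 library 14 to 16 passed in all, and of the 16, 15 kept their call without either FLV border library, 14 without library 1 of WT border and 13 without any one of the other 3. With library totals the median was 0.76 for genes of the nuclear-encoded polymerase, 0.23 for mitochondrial respiration and 0.005 for nuclear photosystem genes. The length offset gave 0.41 for plastid-encoded and 0.27 for nuclear-encoded plastid ribosomal proteins, both then called upward against negative medians before, and the length and GC offset 0.35 for the former, also called, and -0.062 for NAC17. Values spanned 0 without 1 library for TRY (-2.91 to 0.57), LHCA2 (-2.63 to 0.45), LHCB4.2 (-3.59 to 2.35), GLK2 (-2.34 to 0.91), the light-harvesting list (-3.06 to 1.61) and that of the nuclear-encoded polymerase (-0.87 to 0.12).

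With protein-coding genes only, the share in WT centre was 55.4% for nuclear and 43.7% for plastid genes, and the mitochondrial share was 1.75% in FLV border and 0.811% in WT border. Between the comparisons, DESeq2 gave a Pearson correlation of -0.227, a Spearman correlation of -0.159, a covariance of -0.389 and 56 genes in both. The length offset gave a Spearman correlation of -0.061, a covariance of -0.125 and 0 genes in both, and the block 0. Without 1 library the Pearson correlation was -0.368 to -0.034, the Spearman correlation -0.233 to 0.038, the covariance -0.741 to -0.05 (what shared controls alone give there was not simulated) and the genes in both 0 to 6. A log2 change of 2 was recovered in 8.4% and 9.6% of simulated cases, and the parts of depth and of 2 libraries per group in this were not separated.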

Other observations

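Of the tests below, that of the DUF295 family was chosen only after the result was seen. Among genes of the DUF295 domain family, of unknown molecular function, 3 of 28 tested members were called in FLV border against WT border, all higher. With the tandem pair counted once the one-sided Fisher exact p was 9.63e-05, but the family was picked because of these calls, so the test restates them and whether the family is raised stays open. In the family 22 members were higher and 6 lower (median 0.82), with AT5G55270 at 5.07 (adjusted p = 0.125) and AT1G30160 at 4.63 (adjusted p = 0.322) not called. A wider definition of 37 members holds the same 3 called genes. Members can share reads, so the count of independent genes is uncertain.

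The covariance of the fold changes of the 2 comparisons was -0.134, nearer to 0 than the -0.263 of simulations with no group effect (-0.271 to -0.258). A shared direction of the mutant border and of the border-to-centre difference would give this, but so could the settings of the simulations. They gave each gene the same spread in all groups, while the libraries correlated at 0.942 in WT border and 0.859 in WT centre. They also held no effect of library number, while replicate deviations of FLV border and WT border correlated at 0.366. An estimate from the spread of the WT border libraries was -0.201, nearer to the observed value than the simulations are. That estimate used log2 CPM rather than fitted fold changes. Whether there is any shared part is therefore open.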
